A study of Sus scrofa with 6 samples.

How the data were processed

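The data were RNA-seq values of gut tissue from 6 pig samples, 3 Control and 3 SMP, grouped by the treatment given in the labels, with replicate numbers from the sample titles. Per the labels' protocols, libraries were made from total RNA with a NEBNext Ultra kit. The kit's strand setting and the handling of reads that map to several genes are not given in the sources used here, so genes with near-identical copies and overlapping genes are uncertain. Per the submitters' processing notes, the tools were HISAT2 2.0.5, StringTie and DESeq2 1.16.1, with no role or order given, and the genome build is mm10, a mouse build. The gene identifiers in the deposited table are pig Ensembl identifiers, so the build behind the values is not settled, and no coordinates are given.

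The authors deposited 1 value per gene and sample for 21911 genes. These deposited values are FPKM, fragments per kilobase of gene and per 1000000 of the library total, as read from the values themselves: in each library a value is a whole number divided by a gene length and a library total, with 1 length per gene in all 6 libraries. The whole numbers behind the values were recovered for 21911 of 21911 genes (100%) in all libraries, at a relative tolerance of 5e-09. Whether they count reads or read pairs is not stated. The recovered library totals were 15927028 to 20712701, and the listed genes held 98.6% to 99.0% of them. Counting error is therefore small for genes with values well above the floor of 3 reads, and the spread between libraries sets the precision. Of 2940 simulated genes, 98.71% had all 6 counts recovered by the same steps, with all 6 library totals exact. Replicates of a group differed by 13.5 to 111 chi-square units per degree of freedom over genes, so no 2 libraries were the same library deposited 2 times.

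Gene symbols were taken from a table of gene names, which matched 14153 of the 21911 identifiers. TPH1, TNF and IL1B had no identifier under those symbols and were not analysed here. Values were analysed as log2(FPKM + 1), with a pseudocount of 1, for the 11471 genes with a mean of at least 1 FPKM over all libraries. Of these, 9974 had a symbol. The main test was limma 3.58.1 in R 4.3.3, with a linear model of treatment only, an empirical Bayes trend with mean expression, and Benjamini-Hochberg adjustment at 0.05. The plan named a count test for count data and this test for normalized values; the deposited values being FPKM, the latter was used, and the count tests named for count data were not run. Gene lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 37 lists, and with fry and an estimated correlation beside it. A list's mean log2 value per library is the mean of its tested members. The adjustment over a list alone used only the p-values of its tested genes.

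The comparison, the gene lists, the test and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among changed genes with a symbol, a mean of at least 1 FPKM and groups that did not overlap. It also took up to 4 members with the smallest p from each list with a changed gene, up to 2 from each other list, and the genes of the study's question (GCG, GLP2R, GLP1R, DPP4, PCSK1, TJP1, OCLN, CLDN1, MUC2, LGR5, OLFM4, TPH1, IL6, TNF and IL1B) by value. Genes named outside it are said to have been chosen after their values were seen.

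The alternatives fixed beforehand were quantile normalization, no filter and a mean of at least 5, pseudocounts of 0.1 and 0.5, array weights (gene-by-gene method), a robust empirical Bayes fit, the replicate number as a block, an absolute log2 difference of at least 1, and each library left out in turn. Chosen after seeing the data were voom on the recovered whole numbers, median-ratio scaling with and without mitochondrially encoded genes, removal of each library's lowess trend with gene length (span 0.4), leaving out both Control replicate 2 and SMP replicate 3, and the smooth muscle list's mean as a covariate. Principal components used the tested genes, with the 500 most variable as an alternative. Gene families by symbol and 3 added lists (HOX paralogues 1 to 5, HOX paralogues 6 to 13 and pan-leukocyte genes) were used for the closing observations only.

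The limma step was tested on simulated data for SMP against Control over 11471 genes, where it recovered 74 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 8 calls among unchanged genes. Camera called a simulated list of 20 changed genes and did not call a list of 20 unchanged ones. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes are correlated. All simulated genes had the same dispersion (0.031), and the changed ones were drawn only from well-read genes. No simulated library was made to stand apart. The limma figures therefore do not give the recovery or the false calls in the real data, where the spread differed between genes and libraries stood apart. Reading and recovery used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. No sequence, position or exon is given, since no pig genome was used here.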

Results

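RNA was sequenced from gut tissue of 6 pig samples, 3 from a Control group and 3 from a group named SMP. Per the design text of the series, the comparison was between piglets that drank an alkaline mineral water based on metasilicate and Control piglets. The labels give the tissue only as gut, so the segment of the gut, the age and the sex of the piglets were not given in the sources used here. The labels number 3 samples per group and do not say that each came from its own piglet, so the p-values below measure the spread between these samples. The deposited values were FPKM for 21911 pig genes. The library totals behind them, recovered from the steps between the values, were 15927028, 16110473 and 18636198 reads or read pairs in Control replicates 1, 2 and 3 and 20630889, 20712701 and 16816165 in SMP replicates 1, 2 and 3. At these totals, 3 reads in a gene of 2 kb equalled 0.0724 to 0.0942 FPKM, for counting error only. Values below are mean FPKM ± SD over the 3 libraries of a group (n = 3), log2 differences are SMP minus Control on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values are from limma unless a list test is named.

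The comparison asked which genes differed in the gut between piglets given the mineral water and Control piglets. Of 11471 genes tested, 401 were higher and 241 lower in SMP, together 5.6% of the genes. Genes that rose included the phospholipase PLA2G2A, the carboxypeptidase CPO, the Y-linked gene EIF1AY, the ion and acid-base genes CA7, SLC26A3 and OTOP2 and the proglucagon gene GCG. EIF1AY was read in every SMP library and hardly in the Control libraries, as male SMP and female Control samples would give. The labels do not give the sex, and sex and treatment cannot be separated for any changed gene. Genes that fell included ADA, the potassium channel subunit KCNE1, the hormone gene SCT and the calcium-binding protein gene S100G. Among 37 gene lists fixed before the data were examined, lists of cell division, protein folding in the endoplasmic reticulum and cholesterol synthesis were higher in SMP, and lists of the interferon response, plasma cells, macrophages and the proximal small intestine were lower, all with the preset correlation of camera. With an estimated correlation 0 of the 37 lists passed (smallest adjusted p = 0.489). In each of the 642 changed genes the 3 SMP values lay on 1 side of the 3 Control values, which held for 3744 of all tested genes (32.6%, against 10% by chance).

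The counts of changed genes moved with single libraries. Leaving out Control replicate 1, 2 or 3 gave 90 higher and 56 lower, 532 and 526, or 27 and 20. Leaving out SMP replicate 1, 2 or 3 gave 26 and 27, 20 and 23, or 779 and 286. Of the changed genes still tested, each kept its sign in every one of these fits. This had to be so, since the groups did not overlap in any changed gene. The main counts made 62.5% of the changed genes higher. With the libraries rescaled by median ratios the split was 344 higher and 462 lower (42.7% higher), and with the trend of each library with gene length removed it was 377 and 409 (48% higher). The median log2 difference of all tested genes was 0.09.

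The first principal component of the log2 values held 48.5% of the variance and separated the groups, and the second held 24.7%. Control replicate 2 (-38.6 on the second component) and SMP replicate 3 (28.9) lay apart from the others of their groups. SMP replicates 1 and 2 had a Pearson correlation of 0.990 across genes and Control replicates 1 and 3 of 0.977, whereas Control replicate 2 had its highest correlation with SMP replicate 2 (0.948). Correlations across genes describe these libraries, since genes are not independent replicates. Without both Control replicate 2 and SMP replicate 3, an alternative chosen after seeing the data, 1808 genes were higher and 1235 lower, and 632 of the 640 changed genes tested there kept their call.

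**Figure D1:**
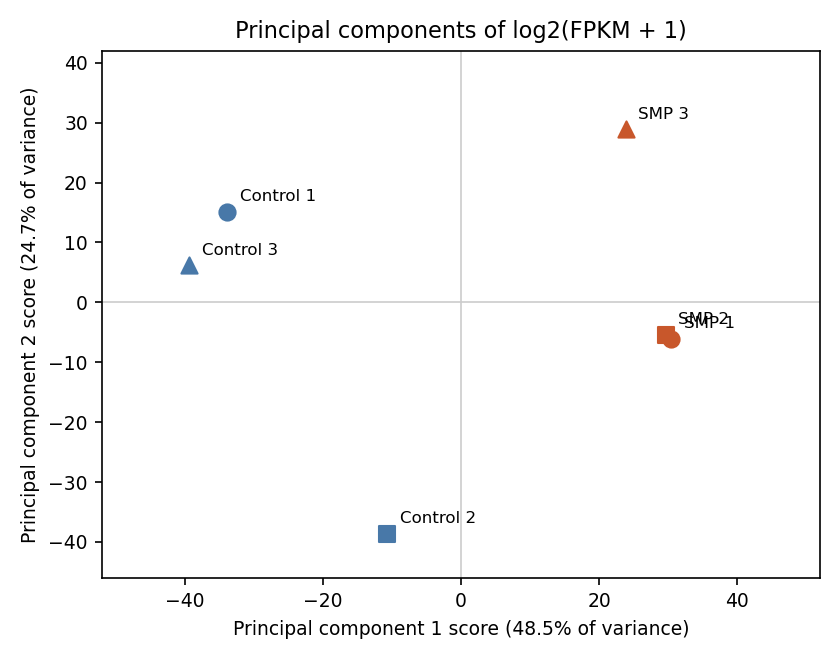
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 11471 genes, in arbitrary units, with Control in blue and SMP in orange and 1 symbol per replicate number. The first component (48.5% of the variance) separates the groups, and Control replicate 2 and SMP replicate 3 lie farthest from 0 on the second, at -38.6 and 28.9.

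Among genes with a symbol, the largest rise was in PLA2G2A (ENSSSCG00000003494), which encodes a secreted phospholipase with antibacterial activity. It was listed at 0 in each Control library, with 0 reads, and at 436, 428 and 35.7 FPKM in SMP replicates 1, 2 and 3 (adjusted p = 0.0122), so no fold is given. CPO (ENSSSCG00000016135), a carboxypeptidase, rose from 0.226 ± 0.185 to 34.2 ± 3.05 (log2 difference 4.85, SE 0.16, adjusted p = 1.71e-05). SLC26A3 (ENSSSCG00000021813), the chloride and bicarbonate exchanger of the intestinal surface, rose from 0.475 ± 0.0956 to 19.9 ± 0.899, 41.8-fold (adjusted p = 1.71e-05). The carbonic anhydrase gene CA7 rose from 0.793 ± 0.488 to 29.98 ± 11.99 and the proton channel gene OTOP2 from 1.31 ± 0.429 to 22.6 ± 1.81, with adjusted p-values of 0.00463 and 3.01e-04. ST3GAL1, PLB1, PAPSS2, CA4 and GPR15LG rose by 2.49 to 3.24 on the log2 scale, with adjusted p-values from 0.0173 to 0.0335.

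Among genes with a symbol, the largest fall was in ADA (ENSSSCG00000021255), encoding adenosine deaminase, from 393 ± 254 to 6.87 ± 1.64 (log2 difference -5.36, SE 0.58, adjusted p = 0.00833). Within Control it ranged from 117 in replicate 2 to 618 in replicate 1. S100G (ENSSSCG00000012147), the intestinal calcium-binding protein calbindin-D9k, fell from 11310 ± 2460 to 1022 ± 248, 11.1-fold (adjusted p = 0.00173), and the calcium channel gene TRPV6 fell from 17.1 ± 9.86 to 0.969 ± 1.05 (adjusted p = 0.0253). The retinoid enzyme genes RDH5 and BCO1 both fell by 3.17 on the log2 scale (adjusted p = 0.0174 and 0.00984). The potassium channel subunit gene KCNE1 fell from 54.7 ± 44.6 to 0.403 ± 0.238, and the trehalase gene TREH from 36.7 ± 6.60 to 5.50 ± 3.46 (adjusted p = 0.0233 and 0.0174). LCN15, FOLH1B and PRDM16 fell by 3.07, fell by 2.78 and fell by 2.68 on the log2 scale.

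EIF1AY (ENSSSCG00000037509), a Y-linked gene of a translation initiation factor, rose from 0.0731 ± 0.1002 to 26.4 ± 2.93 (log2 difference 4.67, adjusted p = 1.71e-05). KDM5D, a Y-linked gene named after its values were seen, had 0 reads in the 3 Control libraries and 128, 149 and 40 reads in SMP replicates 1, 2 and 3. Both genes moved as male SMP and female Control samples would give, so sex and treatment cannot be separated in these samples. Some genes had no symbol in the name table, and 2 of them are given here, chosen after their values were seen. ENSSSCG00000044599 was at 45.8 ± 2.82 in Control and listed at 0 in every SMP library. ENSSSCG00000012178 rose from 0.0218 ± 0.0377 to 32.3 ± 1.29.

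Of the 66 changed genes that are named by rule, 11 kept their call without each single library in turn. These were EIF1AY, SLC26A3, CPO, OTOP2, S100G, ISG15, IFI6, CA7, MZB1, TNFRSF17 and PDK4, with adjusted p-values no higher than 0.0475. The calls of all the others were lost in at least 1 such fit. Without SMP replicate 2 as many as 55 were lost, and 53 without Control replicate 3, 50 without SMP replicate 1, 40 without Control replicate 1 and 4 each without Control replicate 2 or SMP replicate 3.

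**Figure D2:**
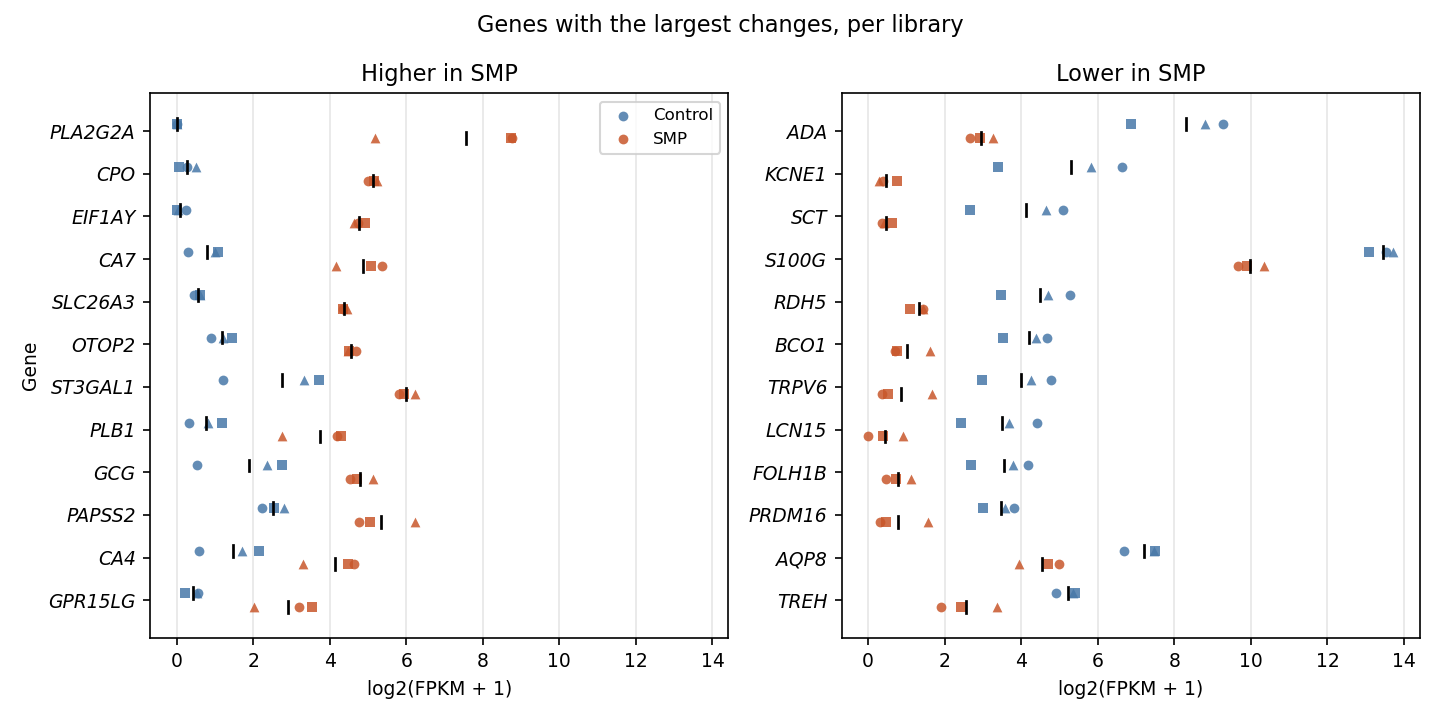
Values of the 12 genes with the largest rise and the 12 with the largest fall in SMP among genes with a symbol, as log2(FPKM + 1) per library (circles, squares and triangles for replicates 1, 2 and 3), with Control in blue, SMP in orange and black lines at the group means. The groups do not overlap in any gene shown, as the rule that chose the genes required. S100G was the most abundant, at 11310 FPKM on average in Control and 1022 in SMP.

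The title of the series names glucagon-like peptide 2, a product of the proglucagon gene GCG, so the genes of that axis were reported by value. GCG (ENSSSCG00000015895) rose from 3.46 ± 2.74 to 27.3 ± 6.05, 7.89-fold (log2 difference 2.92, SE 0.55, adjusted p = 0.0339), and every SMP library (22.3, 25.4 and 34.0) was above every Control library (0.443, 5.81 and 4.12). Its call was lost without Control replicate 3 (adjusted p = 0.115), SMP replicate 1 (0.122), SMP replicate 2 (0.135) or SMP replicate 3 (0.0667). It was also lost with no filter (0.0773), with a pseudocount of 0.1 (0.0631) and with the smooth muscle covariate described below (0.0986). The log2 differences of GCG in these fits were 2.92, 3.5 and 2.85. GLP2R, the receptor of the peptide, was at 1.25 ± 0.167 in Control and 1.45 ± 1.26 in SMP (adjusted p = 0.998), and DPP4, the protease that cleaves it, at 82.1 ± 21.6 and 89.2 ± 37.4 (adjusted p = 0.903). Without both Control replicate 2 and SMP replicate 3, DPP4 passed as lower (log2 difference -0.48, adjusted p = 0.0410). Among the 12 tested genes of the GLP2 axis list, GCG alone passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone. The list did not pass camera (median log2 difference 0.29, adjusted p = 0.609). IGF1R was at 1.76 ± 0.551 in Control and 3.52 ± 0.149 in SMP and HBEGF at 4.13 ± 1.69 and 1.67 ± 0.311, with adjusted p-values of 0.0633 and 0.0941. GLP1R (mean 0.316 FPKM over all libraries) and PCSK1 (0.62), which encodes a prohormone convertase, were below the mean of 1 FPKM needed for a test.

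The hormone genes GIP, SCT and MLN fell while GCG rose. The labels give no gut segment and no sex, so an effect of the treatment on these genes, GCG included, cannot be told apart from either. GIP, made by K cells of the upper small intestine, fell from 96.0 ± 15.5 to 29.6 ± 3.35 (log2 difference -1.66, SE 0.17, adjusted p = 0.00739). The secretin gene SCT fell from 20.7 ± 14.0 to 0.390 ± 0.144 (adjusted p = 0.0235). The motilin gene MLN fell from 2.33 ± 1.42 to 0.0143 ± 0.00535, with 566 reads in all Control libraries and 4 in all SMP libraries (adjusted p = 0.0459). Of 13 tested enteroendocrine genes, 1 rose and 3 fell over all genes, and 1 and 5 when adjusted over the list alone. The list missed the threshold in camera (median -0.19, adjusted p = 0.0555), and passed it without SMP replicate 1 (0.0487), with pseudocounts of 0.1 (0.0337) and 0.5 (0.0443), with the replicate number as a block (0.0413), with the smooth muscle covariate (0.0188) and on ranked statistics (0.0330). The list of serotonin, neuropeptide and stress signalling (10 tested, 0 changed over all genes and 0 when adjusted over the list alone) had a median of -0.07 and an camera adjusted p of 0.212. In it, DDC was at 65.4 ± 13.7 and 40.9 ± 2.52 and the serotonin transporter gene SLC6A4 at 14.1 ± 3.09 and 8.69 ± 1.93 (adjusted p = 0.0902 and 0.121). TPH1 was not analysed here.

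Some markers of the segments of the gut changed between the groups. In the list of the proximal small intestine 2 of 9 tested genes fell, GIP and MLN, and 5 fell when adjusted over the list alone (median -1.14, camera adjusted p = 3.26e-04; adjusted p = 0.527 with an estimated correlation). The iron transport genes of that list did not pass singly. CYBRD1 was at 161 ± 77.5 in Control and 47.2 ± 8.58 in SMP and SLC40A1 at 64.8 ± 51.6 and 4.76 ± 3.37 (adjusted p = 0.0605 and 0.0820). GATA4, a transcription factor of the proximal small intestine and a member named after its values were seen, was at 27.4 ± 4.60 and 27.2 ± 4.86 (adjusted p = 0.971). The mean log2 value of the list was 5.63, 4.26 and 5.28 in Control replicates 1, 2 and 3 and 3.86 to 3.97 in SMP, so that Control replicate 2 was the nearest to SMP.

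In the list of the large intestine 4 of 5 tested genes rose and 1 fell, with the same counts when adjusted over the list alone (median 2.66, camera adjusted p = 0.00470; adjusted p = 0.527 with an estimated correlation). SLC26A3, OTOP2 and CA4 are among those that rose, and the calcium-activated chloride channel gene BEST4, named after its values were seen, rose from 7.34 ± 2.32 to 15.4 ± 1.97 (adjusted p = 0.0490). The water channel gene AQP8 fell from 153 ± 44.0 to 23.3 ± 8.17 (adjusted p = 0.0132). Without both Control replicate 2 and SMP replicate 3 the camera adjusted p of this list was 0.0510. The list of the ileum and bile acid handling had 2 of 7 genes lower, also when adjusted over the list alone, and did not pass (camera adjusted p = 0.294). Its median was -0.10 and its mean 0.09, while its camera direction was down. AMN and NR0B2 fell, by 1.21 and 0.98 on the log2 scale (adjusted p = 0.0300 and 0.0462), and the bile acid-binding protein gene FABP6 was at 0.584, 3.85 and 9.15 in Control and 33.4, 50.8 and 3.60 in SMP (adjusted p = 0.222).

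Genes of ion and water transport moved in both directions. Of 21 tested, 4 rose (SLC26A3, CA4, KCNE3 and, named after its values were seen, SLC4A4) and AQP8 fell, and 7 rose and 1 fell when adjusted over the list alone. The list as a whole did not pass (median 0.26, camera adjusted p = 0.203). KCNE3, a potassium channel subunit used in chloride secretion, rose from 11.7 ± 0.827 to 22.1 ± 3.61 (adjusted p = 0.0336). Of 23 tested genes of enterocyte digestion and absorption, 3 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone (median -0.01, camera adjusted p = 0.222). TREH, AMN and APOA1, which encodes an apolipoprotein and fell from 8470 ± 1684 to 4503 ± 527 (adjusted p = 0.0495), were the 3 that fell, whereas the fatty acid-binding protein gene FABP2 was at 605 ± 172 and 1461 ± 482 (adjusted p = 0.0612). The direction of this list turned with quantile normalization (adjusted p = 0.750), and without SMP replicate 3 it passed as lower (0.00292).

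Interferon-stimulated genes were lower in SMP. Of 23 tested, 8 fell over all genes and 13 when adjusted over the list alone, and none rose (median -0.85, camera adjusted p = 2.06e-09; adjusted p = 0.519 with an estimated correlation). ISG15, a ubiquitin-like protein induced by interferon, fell from 1610 ± 177 to 350 ± 23.9, 4.61-fold (log2 difference -2.20, SE 0.15, adjusted p = 0.00158). IFI6 fell from 1889 ± 151 to 394 ± 64.7, 4.798-fold (adjusted p = 0.00272). DHX58, a regulator of RNA sensing, fell from 54.4 ± 11.99 to 21.7 ± 1.79, and IRF7, a transcription factor of the interferon response, from 273 ± 21.7 to 110 ± 25.2 (adjusted p = 0.0222 and 0.0226). The mean log2 value of the list was 6.75, 5.70 and 6.47 in Control replicates 1, 2 and 3 and 5.41 to 5.48 in SMP.

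Markers of B and plasma cells were lower as a list. Of 9 tested, 4 fell and 1 rose over all genes, and 6 fell and 1 rose when adjusted over the list alone (median -1.26, camera adjusted p = 1.15e-04; adjusted p = 0.489 with an estimated correlation). MZB1, a chaperone of antibody-secreting cells, fell from 83.8 ± 14.4 to 16.8 ± 3.28 (log2 difference -2.26, SE 0.20, adjusted p = 0.00504), and TNFRSF17, the receptor BCMA of plasma cells, from 11.3 ± 2.29 to 1.92 ± 0.518 (adjusted p = 0.00668). POU2AF1 fell by 1.26 and the joining chain gene JCHAIN by 2.13 on the log2 scale (adjusted p = 0.00668 and 0.0343). SPIB, named after its values were seen, was the member that rose, from 13.1 ± 0.233 to 19.7 ± 0.760 (adjusted p = 0.0469).

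Other immune lists were also lower. Of 15 macrophage and mast cell genes none changed over all genes and 4 fell when adjusted over the list alone (median -0.71, camera adjusted p = 2.56e-05; adjusted p = 0.489 with an estimated correlation). AIF1 was at 14.9 ± 2.87 in Control and 7.72 ± 1.83 in SMP and TYROBP at 47.5 ± 10.04 and 27.6 ± 4.22 (adjusted p = 0.0615 and 0.0748). All 9 genes of MHC class II antigen presentation had values below 0 on the log2 scale, 1 fell over all genes and 4 when adjusted over the list alone (median -0.52, camera adjusted p = 1.15e-04; adjusted p = 0.489 with an estimated correlation). SLA-DOA fell from 4.02 ± 0.206 to 1.78 ± 0.422 (adjusted p = 0.0300), and CD74, the invariant chain, was at 907 ± 51.95 and 637 ± 34.8 (adjusted p = 0.0765). The 18 T and NK cell genes included 0 that changed, over all genes or adjusted over the list alone (median -0.31, camera adjusted p = 0.00177; adjusted p = 0.701 with an estimated correlation), and the list did not pass without Control replicate 1 (0.0867). The mean log2 value of the T and NK cell list was 2.66 in Control replicate 2, below every SMP library (2.77 to 2.97), so the groups overlapped. CD4 was at 2.23 ± 0.216 and 1.41 ± 0.0307 (adjusted p = 0.0985). The 17 inflammatory cytokine and NF-kB genes likewise included 0 changed genes in either adjustment (median -0.37, camera adjusted p = 0.00949; adjusted p = 0.653 with an estimated correlation), with the list not past the threshold when genes with a mean under 5 were left out (0.0895). The groups overlapped in the mean log2 value of the inflammatory list, at 3.68 in Control replicate 2 against 3.70 and 3.80 in SMP replicates 1 and 2. TGFB1 was at 18.7 ± 3.10 and 12.7 ± 1.45 and NFKB1 at 10.6 ± 1.57 and 14.9 ± 0.544 (adjusted p = 0.112 and 0.103). IL6 was below the test's minimum (mean 0.09 FPKM), and TNF and IL1B were not analysed here.

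Genes of cell division were higher in SMP. All 21 tested members of the proliferation list had positive log2 differences, 8 rose over all genes and 15 when adjusted over the list alone (median 0.79, camera adjusted p = 2.52e-08; adjusted p = 0.489 with an estimated correlation). TYMS, a thymidylate synthase, rose from 10.2 ± 0.184 to 23.4 ± 1.60 (log2 difference 1.11, SE 0.12, adjusted p = 0.00914), and the topoisomerase gene TOP2A from 14.0 ± 1.45 to 36.0 ± 6.31 (adjusted p = 0.0174). The mitotic genes KIF11 and CENPF rose by 0.93 and 0.98 on the log2 scale (adjusted p = 0.0206 and 0.0221). Of 19 stem cell and Wnt genes, 1 rose over all genes and 4 when adjusted over the list alone (median 0.43, camera adjusted p = 0.00913; adjusted p = 0.608 with an estimated correlation). EPHB2, a receptor of crypt cells, rose from 5.54 ± 0.255 to 17.0 ± 3.50 (adjusted p = 0.0124). The crypt marker OLFM4 was at 761 ± 241 in Control and 1599 ± 285 in SMP, with a log2 difference of 1.10 and all SMP libraries above all Control libraries, but did not pass (adjusted p = 0.0591). It passed with quantile normalization (0.0224), array weights (0.00340) and voom (0.0484), without Control replicate 2 (0.0288) and without both Control replicate 2 and SMP replicate 3 (0.0151). LGR5 (mean 0.6 FPKM) was below the test's minimum.

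Chaperones of the endoplasmic reticulum were higher as well. Of 17 genes of the unfolded protein response, 6 rose over all genes and 10 when adjusted over the list alone (median 0.74, camera adjusted p = 7.81e-05; adjusted p = 0.527 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose from 133 ± 18.8 to 442 ± 65.5, 3.31-fold (log2 difference 1.72, SE 0.18, adjusted p = 0.00775). HYOU1 rose from 16.8 ± 3.89 to 50.4 ± 11.8 and DNAJC3 from 12.5 ± 2.62 to 27.6 ± 1.03 (adjusted p = 0.0237 and 0.0233). Of 17 heat shock genes, 5 rose over all genes, and 7 rose and 1 fell when adjusted over the list alone. That list missed the threshold (median 0.59, camera adjusted p = 0.0555) and passed it without SMP replicate 3 (0.0226), with quantile normalization (0.00297) and with median-ratio scaling (0.0247). HSP90AA1 rose from 210 ± 38.7 to 566 ± 171 and HSPH1 from 19.9 ± 3.46 to 43.4 ± 4.05 (adjusted p = 0.0379 and 0.0233).

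All 20 tested genes of cholesterol synthesis had positive log2 differences, 3 rose over all genes and 9 when adjusted over the list alone (median 0.68, camera adjusted p = 4.42e-05; adjusted p = 0.569 with an estimated correlation). NSDHL rose from 2.43 ± 0.109 to 4.67 ± 0.535, LSS from 14.7 ± 1.55 to 24.5 ± 0.537 and FDFT1, squalene synthase, from 9.14 ± 0.285 to 16.0 ± 2.14, with adjusted p-values of 0.0313, 0.0349 and 0.0353. Of 20 genes of fatty acid oxidation, 1 rose and 2 fell over all genes and when adjusted over the list alone (median 0.005, mean -0.03, camera adjusted p = 0.292, direction down). PDK4, which restrains glucose oxidation, fell from 20.8 ± 3.50 to 5.03 ± 1.11 (adjusted p = 0.00739), and the mitochondrial transferase gene CPT2 rose from 19.95 ± 0.828 to 40.15 ± 8.57 (adjusted p = 0.0370). Of 24 nuclear genes of oxidative phosphorylation, 0 changed in either adjustment (median -0.04, mean 0.004, camera adjusted p = 0.683, direction down and turned with quantile normalization or the length trend removed). UQCRC2 was at 46.6 ± 13.2 and 70.1 ± 2.75 (adjusted p = 0.151).

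**Figure D3:**
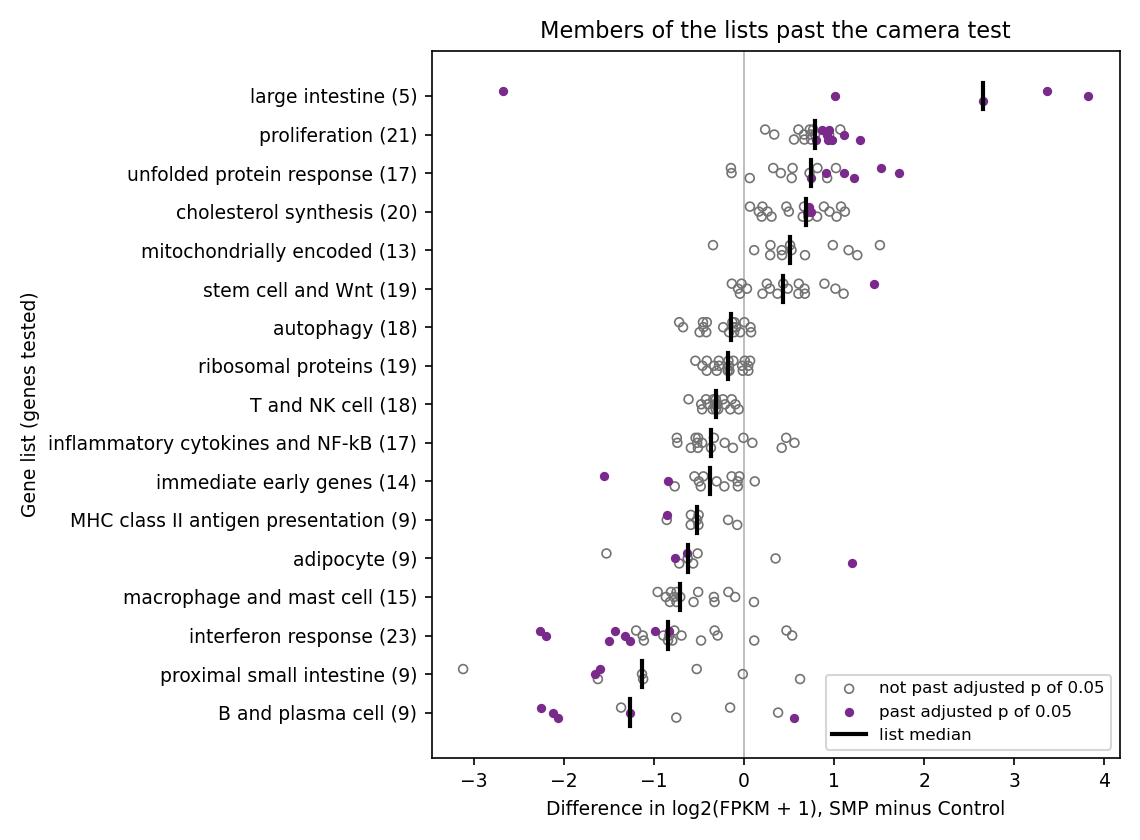
Log2 differences (SMP minus Control, log2(FPKM + 1) scale) of the tested members of the 17 lists past camera at an adjusted p of 0.05, with filled points for genes past the test over all genes, open points for the others and black bars at the list medians. Medians run from 2.66 for the large intestine list to -1.26 for B and plasma cells; the ribosomal protein list turned direction with quantile normalization.

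The lists of the epithelial barrier did not pass camera in the main fit. In the mixed form of fry, which tests change in either direction, the goblet cell (adjusted p = 0.00142) and antimicrobial (0.00576) lists passed. The junction list did not pass it (0.220). Of 19 genes of tight and adherens junctions, 0 changed over all genes and 0 when adjusted over the list alone (median 0.08, mean -0.04, camera adjusted p = 0.375, direction down). TJP1 was at 6.54 ± 1.501 in Control and 9.19 ± 0.744 in SMP (adjusted p = 0.159), OCLN at 16.2 ± 3.06 and 17.5 ± 0.690 (adjusted p = 0.676) and CLDN3 at 1697 ± 159 and 1042 ± 258 (adjusted p = 0.0930). CLDN1 (mean 0.047 FPKM) was below the test's minimum. Of 13 goblet cell and mucus genes, 1 rose in either adjustment (median 0.24, camera adjusted p = 0.812), the glycosyltransferase gene GALNT12, from 1.74 ± 0.533 to 4.92 ± 0.421 (adjusted p = 0.0222). MUC2, the main secreted mucin, was at 37.3 ± 1.31 and 36.2 ± 14.6 (adjusted p = 0.819), and TFF3 at 2012 ± 136 and 883 ± 425 (adjusted p = 0.0944). Of 8 antimicrobial genes, PLA2G2A rose over all genes, and 2 rose and 2 fell when adjusted over the list alone (median 0.15, mean 1.08, camera adjusted p = 0.840). NOS2 was at 2.63 ± 1.28 and 7.65 ± 1.77 and the polymeric immunoglobulin receptor gene PIGR at 932 ± 132 and 648 ± 65.8 (adjusted p = 0.0532 and 0.112).

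Stress and turnover lists moved as follows. Of 14 immediate early genes, 2 fell over all genes and 5 when adjusted over the list alone (median -0.38, camera adjusted p = 2.51e-04; adjusted p = 0.489 with an estimated correlation). FOS fell from 18.5 ± 4.88 to 5.51 ± 0.995 and the phosphatase gene DUSP1 from 38.0 ± 3.79 to 20.8 ± 3.16 (adjusted p = 0.0190 and 0.0370). The 18 autophagy genes included 0 changed genes in either adjustment but passed as a list (median -0.15, camera adjusted p = 8.30e-04; adjusted p = 0.489 with an estimated correlation). OPTN, an autophagy receptor, was at 7.73 ± 0.995 and 4.45 ± 0.608 (adjusted p = 0.0508). Of 18 antioxidant genes, 1 rose and 1 fell over all genes, and 1 rose and 3 fell when adjusted over the list alone (median 0.02, mean -0.04, camera adjusted p = 0.292, direction down). The glutathione peroxidase gene GPX2 rose from 25.9 ± 6.19 to 74.2 ± 10.9 and the quinone reductase gene NQO1 fell from 30.5 ± 4.71 to 13.04 ± 2.62 (adjusted p = 0.0190 and 0.0244).

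Markers of the muscle and nerve layers differed more among Control libraries than between the groups. The mean log2 value of the 18 tested smooth muscle genes was 5.25, 6.73 and 3.11 in Control replicates 1, 2 and 3 and 5.87, 6.31 and 6.23 in SMP replicates 1, 2 and 3. None of these genes changed in either adjustment (median 1.09, camera adjusted p = 0.0816). The list passed without Control replicate 2 (1.27e-05) or SMP replicate 1 (0.0321), and in 8 other fits given in the closing section, among them array weights (0.00164) and quantile normalization (0.0118). ACTG2, enteric smooth muscle actin, was at 238, 425 and 10.3 in Control and 383, 527 and 596 in SMP (adjusted p = 0.313). With this mean as a covariate, an alternative chosen after seeing the data, 36 genes were higher and 30 lower, and 65 of the 642 changed genes kept their call. All 642 kept their sign. The added term leaves fewer residual degrees of freedom, which acts on these counts by construction. The lists of fibroblasts and matrix (20 tested, median 0.46, camera adjusted p = 0.320) and of enteric neurons and glia (18 tested, median 0.40, camera adjusted p = 0.405) had 0 changed genes in either adjustment. Both passed as higher without Control replicate 2 (0.00136 and 4.24e-06), and the fibroblast list also without SMP replicate 1 (0.0296). COL3A1 was at 152 ± 102 and 268 ± 84.5, and VIP at 4.64 ± 2.81 and 7.67 ± 1.26 (adjusted p = 0.302 and 0.231).

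Among the remaining cell types, only the adipocyte list passed camera. Endothelial genes (13 tested, median 0.002, mean -0.02, camera adjusted p = 0.565, direction down) and skeletal muscle genes (3 tested, median 0.53, camera adjusted p = 0.370) had 0 changed genes in either adjustment. KDR was at 2.69 ± 0.597 and 3.40 ± 0.763, and TNNC2 at 3.74 ± 1.87 and 5.50 ± 0.777 (adjusted p = 0.452 and 0.310). The red blood cell and pancreas lists each had 1 tested gene and 0 changes in either adjustment. HBB was at 15.04 ± 3.55 and 7.64 ± 8.19 (list median -1.30, camera adjusted p = 0.292, and 0.0414 without SMP replicate 3), and PNLIPRP2 at 27.1 ± 10.3 and 39.6 ± 12.7 (list median 0.55, camera adjusted p = 0.565). Of 9 adipocyte genes, 1 rose and 2 fell over all genes, and 1 rose and 4 fell when adjusted over the list alone (median -0.63, camera adjusted p = 0.0151; adjusted p = 0.489 with an estimated correlation). The lipoprotein lipase gene LPL rose from 7.08 ± 1.63 to 17.4 ± 2.26, and the lipase gene LIPE fell from 5.08 ± 0.823 to 2.54 ± 0.127 (adjusted p = 0.0246 and 0.0332). The adipocyte list did not pass without Control replicate 2 (0.106), with a mean of at least 5 (0.117), with array weights (0.0649), with the length trend removed (0.0635) or without both Control replicate 2 and SMP replicate 3 (0.145).

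The share of reads in mitochondrially encoded genes was 8.11%, 13.8% and 8.94% in Control replicates 1, 2 and 3 and 13.3%, 11.03% and 14.2% in SMP replicates 1, 2 and 3. Of these 13 genes 0 changed in either adjustment, and the list passed as higher (median 0.51, camera adjusted p = 0.0175; adjusted p = 0.701 with an estimated correlation). It did not pass without Control replicate 1 (0.189), Control replicate 3 (0.0518) or SMP replicate 3 (0.136). ND5 was at 972 ± 500 and 2693 ± 1096 (adjusted p = 0.0775). Of 19 ribosomal protein genes 0 changed in either adjustment, and the list passed as lower (median -0.17, camera adjusted p = 0.00913; adjusted p = 0.713 with an estimated correlation). Its direction turned with quantile normalization (adjusted p = 0.901), and it did not pass without Control replicate 2 (0.185). RPLP1 was at 3106 ± 336 and 2355 ± 481 (adjusted p = 0.245). The rank correlation across genes between gene length and a library's deviation from the mean of all libraries was 0.353 in SMP replicate 3 and -0.211 in Control replicate 2, and lay between -0.178 and 0.033 in the others.

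In camera with its preset correlation 6 lists passed as higher and 11 as lower. With an estimated correlation 0 of the 37 lists passed and the smallest adjusted p was 0.489, with 1 list at an unadjusted p under 0.05. With fry, which tests whether the genes of a list move on balance in 1 direction, 4 lists passed: proliferation (adjusted p = 0.0451) and large intestine (0.00764) as higher, and B and plasma cells (0.0293) and MHC class II (0.0451) as lower.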

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

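Voom, median-ratio scaling, the length trend, the fits without both libraries that stand apart and with the smooth muscle covariate were chosen after seeing the data. Count tests, upper-quartile scaling and voom with quality weights were planned for counts and were not run, as the values are FPKM. All changed genes that were tested kept their sign in all 21 other fits. With a library left out, or another filter, pseudocount or threshold, this had to be so, since the groups did not overlap in any changed gene.

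Against 401 genes higher and 241 lower, the counts were 158 and 100 with no filter, 241 higher with a mean of at least 5, 2933 and 1436 with array weights, 141 and 135 at an absolute log2 difference of at least 1, 1808 and 1235 without both libraries that stand apart, and 36 and 30 with the smooth muscle covariate. Lower genes numbered 462 with median-ratio scaling, 464 with it and without mitochondrial genes, and 409 with the length trend removed. Leaving out 1 library gave 20 to 779 higher and 20 to 526 lower. Fewer samples and, with no filter, more genes tested (21911) act on these counts by construction. So do the added terms of the covariate and replicate block fits, which leave fewer residual degrees of freedom. Otherwise the cause was not tested. With the replicate number as a block the counts were 115 and 121; deviations of same-numbered libraries correlated at -0.306, 0.32 and -0.037, so the numbers do not pair the samples, and not every sample correlated best with its own number. No list lost its call under the block.

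Against 6 lists higher and 11 lower, array weights gave 10 higher, an estimated correlation 0 and 0, and fry 2 and 2. Leaving out 1 library gave 5 to 9 higher and 9 to 13 lower. The first principal component held 79.4% without both libraries that stand apart, 60.1% over the 500 most variable genes and 46.0% to 61.9% with 1 library left out, against 48.5%.

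GCG kept its sign and lost its call with no filter (adjusted p = 0.0773), a pseudocount of 0.1 (0.0631), the covariate (0.0986) and in 4 of the 6 fits with 1 library left out. Not past the test at first, OLFM4 passed in 5 fits, with array weights giving 0.00340, and TJP1 passed with array weights (0.0325).

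Apart from fry and the estimated correlation, these lists lost their call. The T and NK cell list did so with a mean of at least 5 (adjusted p = 0.0605), without Control replicate 1 (0.0867) and with the covariate (0.0539), and the inflammatory list with a mean of at least 5 (0.0895), the length trend removed (0.0743) and the covariate (0.0501). The mitochondrially encoded list did so with no filter (0.132), the covariate (0.109), ranked statistics (0.0664) and without Control replicate 1 (0.189), Control replicate 3 (0.0518) or SMP replicate 3 (0.136). The ribosomal protein list did so with array weights (0.0601), the length trend removed, without Control replicate 2 (0.185) and without both libraries (0.491), and the adipocyte list with a mean of at least 5 (0.117), array weights (0.0649), the length trend removed (0.0635), without Control replicate 2 (0.106) and without both libraries (0.145). The large intestine list did so without both libraries (0.0510).

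Other lists gained a call. Heat shock passed in 12 fits, from quantile normalization (0.00297) to ranked statistics (0.0417). Smooth muscle passed with quantile normalization (0.0118), a mean of at least 5 (0.0455), array weights (0.00164), the replicate block (0.00373), median-ratio scaling (0.0269), the same without mitochondrial genes (0.0276), the length trend removed (0.0288), without both libraries (0.00508), and without Control replicate 2 (1.27e-05) or SMP replicate 1 (0.0321). Array weights and the fit without both libraries gave calls to neuron and glia (0.00672 and 3.09e-04) and enterocyte genes (0.00128 and 2.92e-04), array weights to fibroblasts (0.0391), and the fit without both libraries to tight junctions, as lower (0.0146). Ion transport passed with quantile normalization (0.0350), the covariate (0.0450) and ranked statistics (0.00383), and red blood cell genes with no filter (0.0175). The covariate gave calls, as lower, to endothelial (0.0173) and serotonin (0.0389) genes. The cause was not tested.

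Signs turned in results that were not past the test in the first fit, and in the ribosomal protein list. GLP2R (main 0.00) was at -0.19 with quantile normalization, -0.12 and -0.04 with pseudocounts of 0.1 and 0.5, -0.30 with array weights, -0.23 with voom, -0.05 with both median-ratio scalings, -0.12 with the length trend removed, -0.44 without both libraries that stand apart and -0.01 with the covariate. DPP4 was at -0.34 with array weights, -0.03 with both median-ratio scalings and with the length trend removed, and -0.48 without both libraries, where it passed as lower (adjusted p = 0.0410). OCLN was at -0.01 with the length trend removed and -0.03 without both libraries, MUC2 at 0.26 and EGFL7 at 0.01 with array weights, and at 0.27 and 0.15 without both libraries. With 1 library left out, GLP2R ranged from -0.39 to 0.30, DPP4 from -0.24 to 0.30, OCLN from -0.03 to 0.22 and MUC2 from -0.37 to 0.24.

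Directions of lists turned as follows, with the adjusted p in the turned fit. Quantile normalization turned the enterocyte (0.750), oxidative phosphorylation (0.155) and ribosomal protein (0.901) lists, and no filter the pancreas list (0.418). Array weights turned the endothelial (0.562) and ion transport (0.871) lists. Voom turned the antimicrobial list (0.863), and removing the length trend the oxidative phosphorylation list (0.670). Without both libraries that stand apart the endothelial (0.453), GLP2 axis (0.931), ion transport (0.422) and oxidative phosphorylation (0.695) lists turned. The covariate turned the antimicrobial (0.918), neuron and glia (0.187), fibroblast (0.190) and oxidative phosphorylation (0.706) lists, and fry the endothelial (0.992) and oxidative phosphorylation (0.816) lists. With 1 library left out, directions turned in 7 lists. In the turned fits the adjusted p was 0.936 (antimicrobial), 0.397 (endothelial), 0.682 (GLP2 axis) and 0.911 (goblet cell). It was 0.936 and 0.639 (neuron and glia), 0.613 and 0.903 (fibroblast) and 0.613 and 0.682 (oxidative phosphorylation). Over all fits with 1 library left out, turned or not, it ranged from 0.431 to 0.936 (antimicrobial) and 0.0754 to 0.931 (endothelial). The ranges were 4.24e-06 to 0.936 (neuron and glia), 0.00136 to 0.903 (fibroblast) and 0.406 to 0.682 (GLP2 axis). They were 0.241 to 0.982 (goblet cell) and 0.331 to 0.682 (oxidative phosphorylation). The 4.24e-06 and 0.00136 came without Control replicate 2, where both lists kept their direction. The cause of the turned directions was not tested. Depth limits genes near the floor of 3 reads, such as MLN in SMP (4 reads).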

Other observations

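The gene families and the tests of the enterocyte list and of each list mean against the interferon mean were chosen after the results were seen. Gene families were grouped by symbol. Of 17 families tested, 5 passed camera with its preset correlation and 0 with an estimated correlation. Nucleoporins, the proteins of the nuclear pore, had 7 of 20 tested genes higher and none lower, with 13 not past the test (median log2 difference 0.55, camera adjusted p = 1.10e-06; adjusted p = 0.486 with an estimated correlation), with NUP205 from 2.48 to 5.93 FPKM (adjusted p = 0.0174). Of 6 subunits of the cytosolic chaperonin, 2 rose (median 0.55, camera adjusted p = 9.50e-04; adjusted p = 0.486 with an estimated correlation), TCP1 from 5.17 to 13.2 and CCT3 from 67.3 to 110 (adjusted p = 0.00739 and 0.0388). Both families kept their direction under the 4 scaling alternatives. Of 7 carbonic anhydrases 4 rose (camera adjusted p = 0.0280; adjusted p = 0.486 with an estimated correlation), and beside CA4 and CA7 these were CA13, from 0.623 to 4.66, and CA12, from 0.784 to 2.11 (adjusted p = 0.00411 and 0.0319).

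Single members of the cytochrome P450, glutathione transferase and TMEM families fell. Of 12 cytochrome P450 genes 4 fell, with CYP27A1, which acts in bile acid synthesis, from 15.4 to 3.41 and CYP2D6 from 230 to 78.9 (adjusted p = 0.00718 and 0.0264), while the family did not pass (camera adjusted p = 0.101). The glutathione transferases passed as lower with 1 of 5 genes changed (camera adjusted p = 0.0165; adjusted p = 0.486 with an estimated correlation). TMEM176A fell from 185 to 34.2 and TMEM176B from 185 to 40.8 (adjusted p = 0.00297 and 0.00469), a pair of related genes, so that the split of reads between them is uncertain. The 132 genes named TMEM, of which 1 rose and 7 fell, had a median of -0.06 on the log2 scale (camera adjusted p = 0.0286; adjusted p = 0.644 with an estimated correlation), and of -0.12 with the length trend removed, where the camera adjusted p was 0.0721. The gene ENSSSCG00000050793, with no symbol, was at 37884 FPKM in SMP replicate 3, 2920 in SMP replicate 2 and 73.2 to 192 in the other libraries.

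The first pattern is the rise of large intestine genes beside the fall of proximal small intestine genes, for which an effect of the mineral water stays open, since the labels do not give the position sampled. The length trend as the whole cause is argued against: with it removed the medians were 2.77 and -1.24, against 2.66 and -1.14 before, and the larger camera p of the 2 lists was 0.000576 with the preset correlation, though neither list passed before the correction with an estimated correlation (adjusted p = 0.527 for each). For tissue from the large intestine in place of the small intestine, a bound of -1 was set on the median of the enterocyte list. The bound was set after that median had been seen, so meeting it cannot decide on its own. The median was -0.01 (95% bootstrap interval over genes -0.16 to 0.11) with 11 members above 0 and 12 below. As a set these genes thus did not fall as far as the bound. The interval leaves out the spread between libraries. That median was lower, and the list passed as lower, without SMP replicate 3 (-0.26, adjusted p = 0.00292), with array weights (-0.29, 0.00128) and without both libraries that stand apart (-0.34, 2.92e-04), all still above the bound, and the lowest SMP library was 0.67 below the highest Control library in the mean of the list. The mean log2 value of the enterocyte list was 7.49, 7.27 and 7.71 in Control replicates 1, 2 and 3. In SMP replicates 1, 2 and 3 it was 7.04, 7.27 and 7.77. These values of small-intestinal genes overlap, so they argue against all SMP tissue having come from the large intestine alone. A different position along the gut short of that stays open. HOX paralogues 6 to 13, which are ordered along the gut, had a median of 0.34 over 4 tested genes, none past the test and too few to decide. HOXC8 was left out because its rise (from 0.186 to 2.33 FPKM, adjusted p = 0.0175) had been seen before the test was set. HOX paralogues 1 to 5 had a median of 0.08.

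The second pattern is EIF1AY, read in SMP and hardly in Control. Piglets of different sex in the groups would give this, and the prediction set beforehand for that explanation was met. Of Y-linked genes other than EIF1AY with a symbol and reads, 1 was found, KDM5D. It was at least 5 times higher in every SMP library than in every Control library (0 reads in Control). Sex and treatment therefore cannot be separated in these samples, and how many of the 642 changed genes differ with sex was not tested.

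The third pattern is the lower interferon response in SMP, for which an effect of the treatment, of sex or of position stays open. Fewer leukocytes cannot be told apart from a change within cells: the pan-leukocyte list had a median of -0.49 against -0.85, a difference of 0.36 (95% bootstrap interval over genes 0.19 to 0.71), which met the bound set beforehand against this cause. That bound left out the spread between libraries, and the leukocyte mean minus the interferon mean overlapped between the groups, at -1.83 in Control replicate 2 and -1.84 in SMP replicate 1. Measured in this way the T and NK cell list separated the groups (smallest SMP minus largest Control value 0.40), whereas the macrophage (-0.27) and B and plasma cell (-0.995) lists did not. A smaller share of all cells other than the epithelium cannot be told apart either: the medians of the smooth muscle (1.09), fibroblast (0.46) and neuron (0.40) lists lay above 0, but their means minus the interferon mean overlapped between the groups (-0.57, -0.43 and -0.59), as did the endothelial one (-0.26), in each case through Control replicate 2.

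Other splits of the 6 libraries into 3 and 3 gave at most 0 changed genes against 642 in the real split, and only 1 of the 10 splits gave as many, but 10 splits are too few for a share under 0.05.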
